A study of Pseudomonas chlororaphis subsp. aureofaciens 30-84 with 5 samples.

How the data were processed

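Strand-specific RNA-seq libraries of Pseudomonas chlororaphis subsp. aureofaciens 30-84 were made from 3 wild-type and 2 SCV mutant cultures. Replicates came from separate colonies, per the labels' protocols, so the p-values measure the spread between cultures. Cells grew in AB medium with 2% casamino acids at 28 °C to an OD600 of about 1.8. Ribosomal RNA was depleted before 300 ng of RNA was fragmented, per the labels, which also give a size selection of 200 to 300 bp. The labels name both a SOLiD Total RNA-Seq kit read in pairs on a SOLiD 5500xl and an Illumina TruSeq kit, and the files do not say which was used. The aligner, the counting tool, the filters and the genome build are not given in the sources used here.

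The deposited table holds RPKM values per the file headers, with 1 column per library and 2 decimals. It has 5961 lines of genes, of which the 2 with a repeated locus tag were left out. Gene names came from the table (2101 symbols) and, by old locus tag, from a RefSeq gene table of assembly ASM28191v1 (5861 matches), which together named 2308 genes. That reference was used only for names, gene order and coding length, and no coordinates are given. In all, 20 locus tag numbers were skipped.

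RPKM multiplied by gene length is a whole multiple of the value of 1 read, so the depth of each library could be recovered. It was searched in steps of 500 reads on genes up to 1500 bases and 60 RPKM. At the best depth 85.9% to 92.7% of the informative values were whole within 0.02 reads plus rounding, against 13.3% to 15.7% when the depth was set 1% off. The recovered depths, which are the RPKM denominators and which the labels do not define, were 13719000, 14629000 and 10839500 reads for wild type and 19868000 and 20345500 for SCV. In 3 simulated libraries the search was off by less than 0.1%. RPKM values are not counts, so no count model was used.

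Values were compared as log2(RPKM + 1) in limma 3.58.1 (R 4.3.3; lmFit, then eBayes with trend) for the 5729 genes with a mean of at least 5 RPKM over all libraries. Fold changes are on that scale, which understates changes of genes with low values. Adjusted p-values are limma's, adjusted by Benjamini-Hochberg over all tested genes, all tests are 2-sided, and the threshold was 0.05. The fit had 3 residual degrees of freedom and a prior of 7.59. In 10 simulations on the same 5729 genes, with 200 changed genes each, 76.8% of changes of 0.5 on the log2 scale, 99.0% of changes of 1 and 100% of changes of 2 were recovered, and 6.12% of the calls were false. The simulated noise was normal and independent between genes, and far more genes passed in the data (63.7%), so these rates may not carry over. All designs, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

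Gene lists, 21 in all, were matched by symbol or product name. The 20 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Of these, 11 passed, 3 up and 8 down. With an estimated correlation 0 passed, the lowest adjusted p being 0.766. In the 11 lists that passed, the estimate ran from 0.019 to 0.40, all above the preset. That form also takes its p-values on the 3 residual degrees of freedom of the fit, and both raise p. The fry test, which asks whether the genes of a list move on balance in the same direction, passed for 16 lists, and its mixed form, for change in either direction, for 20. Neither compares a list with other genes. Some symbols are shared by unrelated genes (hrpA and hrpB are also helicases, and choline contains holin), and without these 11 lists passed again.

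Runs were counted as at least 4 consecutive tested genes in locus tag order past the threshold in the same direction, and compared with 1000 shuffles of gene order. Slopes along gene clusters were fitted by regression of log2 fold change on position for 41 clusters in textbook order, of which 39 had at least 3 tested genes. Named genes were chosen by a rule: the 12 highest and 12 lowest fold changes among genes past the threshold, with a mean of at least 20 RPKM and groups that do not overlap; up to 4 members with the smallest p in each list; a fixed set (yfiR, yfiN, yfiB, fleQ, phzR, phzI, gacA, gacS, rpoS, algD and fliC, with yfiN found under the label dgcN); and the ends of the 8 longest runs. Other genes are named as chosen after their values were seen. Alternatives changed the pseudocount (0.1 or 10), the filter (none or 20 RPKM), the scaling (median centring, quantile normalization, or rescaling without genes above 5000 RPKM), the variance model, array weights, a block on the replicate number, and each library in turn. Further alternatives were added after the data were seen: without the silent block, without RNA genes that code for no protein, voom on estimated reads, lists without shared names and an estimated correlation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.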

Results

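RNA from Pseudomonas chlororaphis 30-84, a plant-associated bacterium that makes phenazine antibiotics, was sequenced in wild type (n = 3) and in a mutant that the labels call SCV (n = 2). SCV is the usual abbreviation for a small-colony variant, and the labels do not name the mutation. All cultures grew at 28 °C in AB minimal medium with 2% casamino acids to an OD600 near 1.8. The 5 libraries held RPKM values for 5961 lines of genes. The depth recovered from the values (the denominator of the RPKM, which the labels do not define) was 13719000, 14629000 and 10839500 reads in the wild-type libraries and 19868000 and 20345500 reads in the SCV libraries. At that depth 1 read on a 1-kb gene was worth 0.0492 to 0.0923 RPKM. Across genes, log2 values correlated at 0.987 to 0.996 (Pearson) within groups and at 0.873 to 0.878 between groups, and genes are not independent replicates. The leading principal component, which parted the groups, took 92.3% of the variance.

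The comparison asked which transcripts differ between the SCV mutant and its wild type. Of 20 gene lists tested with camera at a preset correlation, those for amino acid breakdown, iron uptake and ribosomal and transfer RNA passed as higher in SCV. Those for phenazines, other antimicrobial metabolites, type VI secretion, respiration, ribosomal proteins, chemotaxis, flagella and cyclic di-GMP passed as lower. With an estimated correlation 0 lists passed (lowest adjusted p = 0.766). In the 11 lists that passed at the preset of 0.01, the estimate ran from 0.019 to 0.40. That form also rests on 3 residual degrees of freedom, and both raise p. The list calls therefore hold only where members are taken as nearly independent. The calls for ribosomal proteins, chemotaxis and cyclic di-GMP each ended under 1 other alternative. The leucine-breakdown gene liuA rose from 20.6 ± 0.588 RPKM (SD, n = 3) in wild type to 399.9 ± 11.5 RPKM (SD, n = 2) in SCV, and the phenazine gene phzE fell from 1295 ± 124 to 329 ± 24.8 RPKM. A block of 39 neighbouring genes was near 0 in both SCV libraries. Of 5729 genes tested with limma, 3651 (63.7%) passed an adjusted p of 0.05, 2236 higher and 1415 lower in SCV. With at least a 2-fold change there were 1028, 700 higher and 328 lower. The groups did not overlap for 4318 of the tested genes (75.4%, where chance gives 20%). An exact permutation test of 3 against 2 libraries cannot go below 0.1, so no such test was used for single genes.

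The balance of higher and lower genes depended on the scaling of the libraries. The values as deposited gave 61.2% of calls higher in SCV. Centring each library on its median moved every log2 fold change by -0.23 and gave 1611 genes higher and 2292 lower (41.3% higher). Quantile normalization moved the median by -0.14 and gave 1701 higher and 1887 lower (47.4% higher). Leaving out genes above 5000 RPKM and rescaling moved it by -0.11 and gave 1898 higher and 1800 lower (51.3% higher). No gene called as deposited was called in the opposite direction under these 3 scalings, and 3026, 3057 and 3312 of the 3651 calls were shared. The medians of the 8 lists that passed as lower ran from -0.61 to -0.17 as deposited and from -0.84 to -0.41 with centring. The direction of a change smaller than these shifts can depend on the scaling. The flagella and cyclic di-GMP medians (-0.19 and -0.17 as deposited) were smaller than the centring shift. They were -0.42 and -0.41 with centring. All 3 scalings moved the median fold change down, so that these medians stayed negative does not test their direction.

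**Figure D1:**
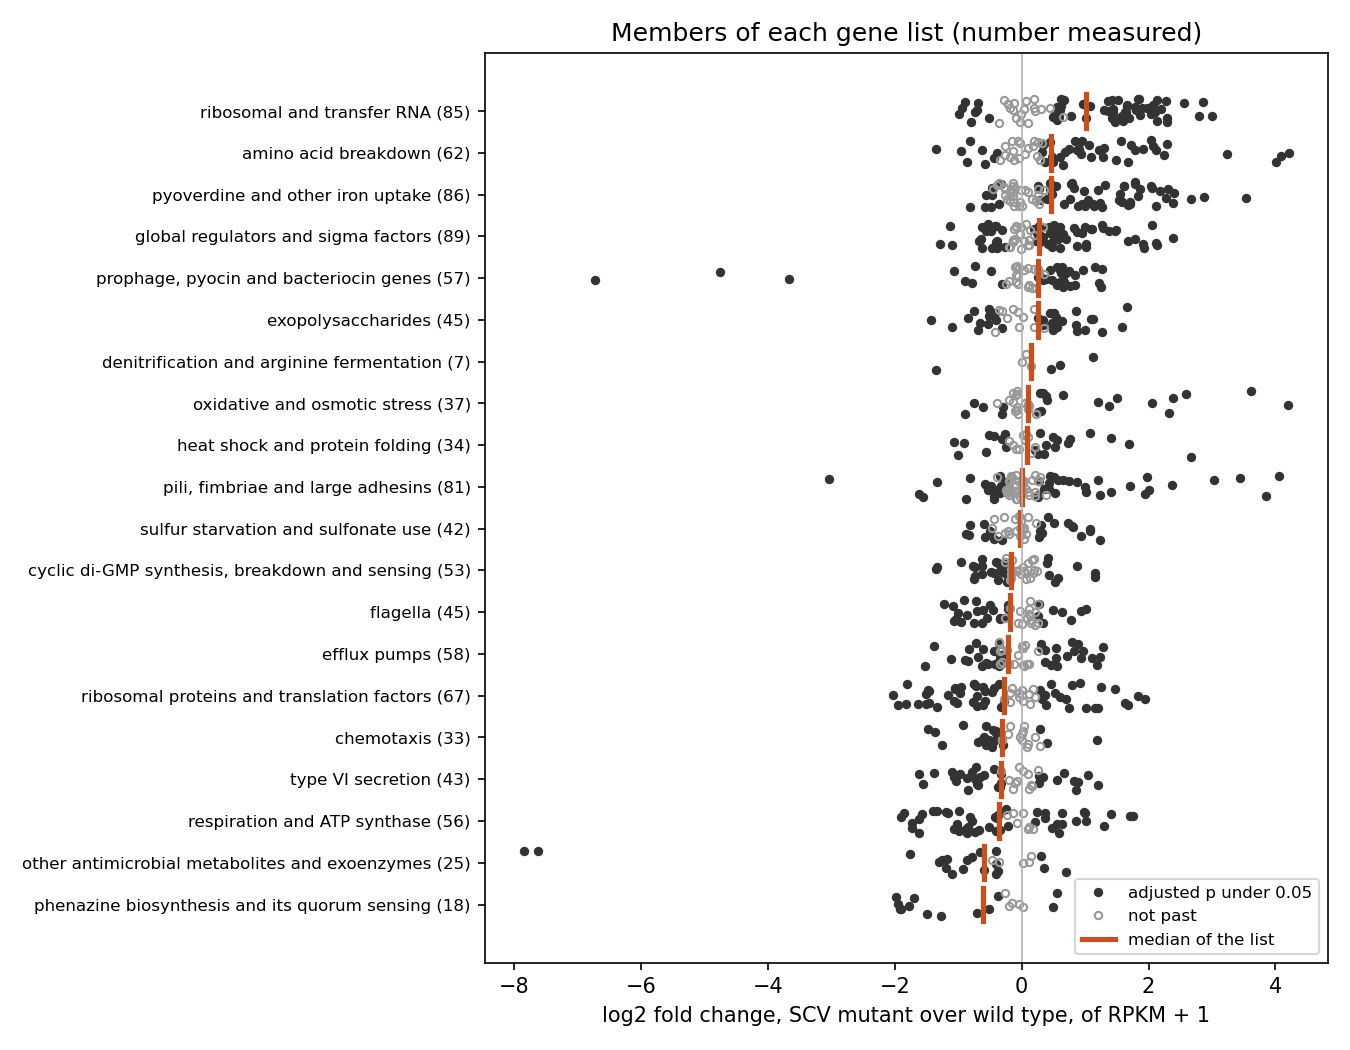
Each point is a gene of a list fixed before the data were examined, placed by its log2 fold change (SCV over wild type, of RPKM + 1), with filled points past an adjusted p of 0.05 and a bar at the list median. Medians ran from -0.61 for phenazines to 1.01 for ribosomal and transfer RNA, and those of the oxidative stress, heat shock, denitrification and pilus lists changed sign under at least 1 other scaling.

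Amino acid breakdown genes rose more often than they fell. Among 62 measured genes of the list, 35 rose and 8 fell, with a median log2 fold change of 0.47 (camera adjusted p = 0.00518; adjusted p = 0.766 with an estimated correlation). With centring 30 rose and 17 fell and the median was 0.23. In that list 43 of them passed over all genes tested and 43 when adjusted over the list alone. The genes for leucine breakdown led it. They were liuA (log2 fold change 4.22, SE 0.084, adjusted p = 2.08e-11), which encodes isovaleryl-CoA dehydrogenase, and liuB, liuC and liuD, with log2 fold changes of 4.09 (adjusted p = 4.80e-11), 4.01 (adjusted p = 7.63e-11) and 3.24 (adjusted p = 1.02e-09). The gene for maleylacetoacetate isomerase in tyrosine breakdown, maiA, rose from 30.4 ± 0.736 to 609.7 ± 77.1 RPKM (log2 fold change 4.28, SE 0.095, adjusted p = 5.14e-11). The largest increase among all genes that the rule for named genes covered was in metE, for the methionine synthase that needs no cobalamin. It rose from 9.97 ± 0.704 to 219.9 ± 21.1 RPKM (log2 fold change 4.33, SE 0.105, adjusted p = 1.09e-10). The methylglyoxal synthase gene mgsA rose to 236 ± 5.32 from 16.8 ± 1.02 RPKM (log2 fold change 3.74, SE 0.092, adjusted p = 1.22e-10). The 12 genes with the highest fold change by the rule also took in a major facilitator transporter (Pchl3084_1492, 3.72 (adjusted p = 1.75e-09)), an ankyrin repeat protein (Pchl3084_5137, 3.72 (adjusted p = 2.33e-08)) and a sugar transporter permease (Pchl3084_4487, 3.70 (adjusted p = 1.37e-09)).

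Iron uptake genes rose more often than they fell. The list for pyoverdine, the fluorescent siderophore, and other iron uptake had 86 measured genes, of which 49 rose and 8 fell, with a median log2 fold change of 0.46 (camera adjusted p = 0.00301; adjusted p = 0.766 with an estimated correlation). With centring 41 rose and 20 fell and the median was 0.23. In this list 57 of them passed over all genes tested and 57 when adjusted over the list alone. Pyoverdine synthesis gene pvdA rose from 14.8 ± 0.533 to 115 ± 6.17 RPKM (log2 fold change 2.88, SE 0.096, adjusted p = 1.37e-09). The TonB energy-coupling genes exbB and exbD rose by log2 fold changes of 2.66 (adjusted p = 2.43e-08) and 2.40 (adjusted p = 7.50e-09). The sigma factor genes pvdS and fpvI, which act in pyoverdine synthesis and uptake, had log2 fold changes of 2.39 (adjusted p = 1.57e-07) and 2.12 (adjusted p = 4.76e-08). The list also took acsA by its symbol, but the product is an acetate-CoA ligase of central metabolism, with a log2 fold change of 2.18 (adjusted p = 4.84e-09). Without such shared names the list call held (adjusted p = 0.00152).

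Single genes for peroxide defence rose, although their list did not pass. Of 37 genes for oxidative and osmotic stress, 16 rose and 5 fell (camera adjusted p = 0.318; adjusted p = 0.766 with an estimated correlation), and 21 of them passed over all genes tested and 20 when adjusted over the list alone. With the replicate number as a block the list passed (adjusted p = 0.0291, over a range of 0.0291 to 0.453 in all alternatives). That block takes wild type replicate 3 out of the fold change. The list mean was 0.55 and its median 0.10, which became -0.13 with centring, -0.028 with quantile normalization and -0.0065 with rescaling. The balance of 16 to 5 became 10 higher and 12 lower with centring, 10 and 9 with quantile normalization and 13 and 7 with rescaling. Alkyl hydroperoxide reductase gene ahpF rose from 57.2 ± 13.4 to 1044 ± 93.6 RPKM (log2 fold change 4.19, SE 0.165, adjusted p = 4.84e-09), and its partner ahpC had a log2 fold change of 2.59 (adjusted p = 1.77e-08). Catalase gene katA rose from 531 ± 63.9 to 2755 ± 52.1 RPKM (log2 fold change 2.38, SE 0.107, adjusted p = 1.29e-08). Thioredoxin reductase gene trxB had a log2 fold change of 2.32 (adjusted p = 1.85e-08). The peroxide-sensing regulator gene oxyR, chosen after its values were seen, rose by 1.38 (adjusted p = 1.61e-07) on the same scale.

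Genes for antimicrobial metabolites fell more often than they rose. In the list for phenazine biosynthesis and its quorum sensing, 11 of 18 genes fell and 2 rose, with a median log2 fold change of -0.61 (camera adjusted p = 9.93e-05; adjusted p = 0.766 with an estimated correlation), and 13 of them passed over all genes tested and 14 when adjusted over the list alone. A run of 8 neighbouring genes from phzA to phzO was lower, with a median of -1.83. Camera at the preset correlation of 0.01 treats such neighbours as nearly independent. In that run the biosynthetic genes phzB, phzC, phzE and phzF fell, with log2 fold changes of -1.70 (adjusted p = 3.37e-08), -1.94 (adjusted p = 1.36e-08), -1.97 (adjusted p = 3.29e-08) and -1.92 (adjusted p = 3.52e-08). The quorum-sensing pair that controls them did not pass. Regulator gene phzR was at 194 ± 15.0 RPKM in wild type and 174 ± 4.73 in SCV (log2 fold change -0.16, SE 0.090, adjusted p = 0.149). It passed as lower with centring (-0.39), quantile normalization (-0.35), rescaling (-0.27) and without wild type replicate 1 (-0.22). The autoinducer synthase gene phzI was at 197 ± 4.64 and 201 ± 2.40 RPKM (log2 fold change 0.025, SE 0.078, adjusted p = 0.800), and its sign turned to -0.21 with centring (now past the threshold), -0.17 with quantile normalization and -0.085 with rescaling. For other antimicrobial metabolites and exoenzymes, 17 of 25 genes fell and 3 rose, with a median of -0.60 (camera adjusted p = 5.35e-05; adjusted p = 0.766 with an estimated correlation), and 20 of them passed over all genes tested and 22 when adjusted over the list alone. Pyrrolnitrin gene prnD fell from 862 ± 62.5 to 348 ± 31.4 RPKM (log2 fold change -1.31, SE 0.095, adjusted p = 5.14e-07), and darB, for resorcinol synthesis, had a log2 fold change of -1.75 (adjusted p = 1.12e-07). Its neighbours darA and darC, chosen after their values were seen, had log2 fold changes of -1.26 (adjusted p = 2.88e-06) and -1.17 (adjusted p = 9.20e-06). The insecticidal toxin genes tcdA1 and tcdC1 of this list lay in the block near 0, with log2 fold changes of -7.85 and -7.63. They lower the list mean, which was -1.11 against the median of -0.60. With the block left out, 11 lists passed again.

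**Figure D2:**
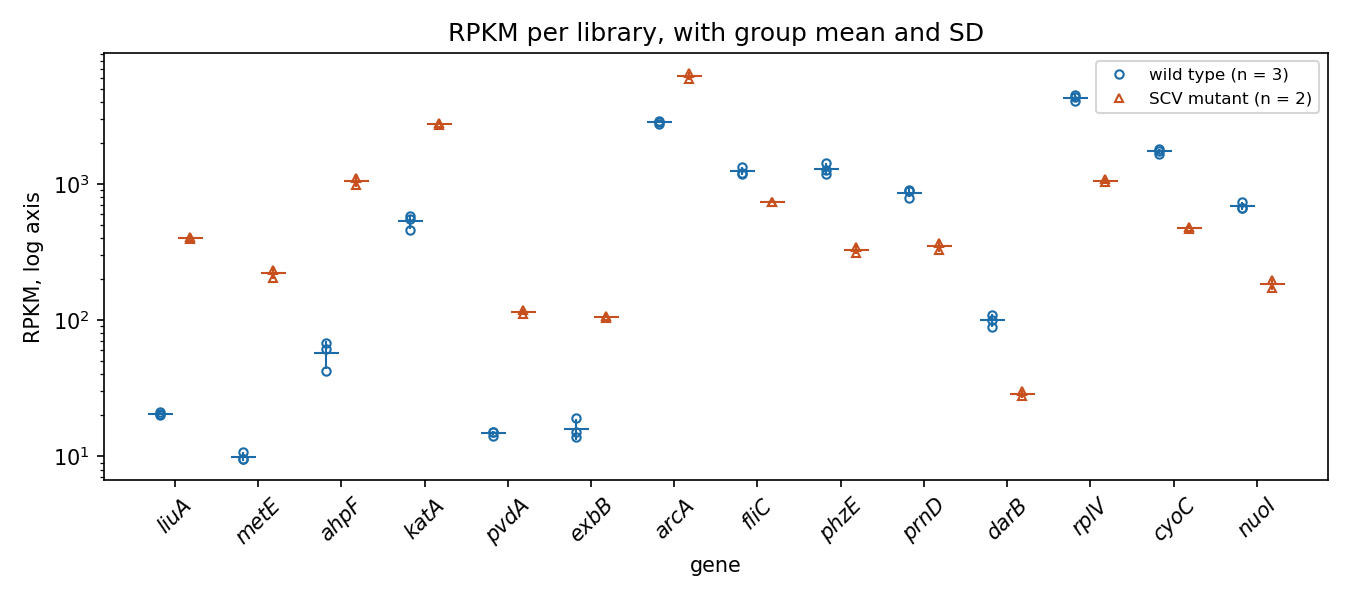
RPKM on a log axis for 14 genes in each library of wild type (circles, n = 3) and SCV (triangles, n = 2), with the group mean and SD. All SCV libraries lie above all wild-type libraries from liuA to arcA, and below them from fliC to nuoI.

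Motility genes were lower on balance. For flagella, 21 of 45 genes fell and 8 rose, with a median log2 fold change of -0.19 (camera adjusted p = 0.0220; adjusted p = 0.799 with an estimated correlation), and 29 of them passed over all genes tested and 29 when adjusted over the list alone. Flagellin gene fliC fell from 1242 ± 81.3 to 734 ± 3.05 RPKM (log2 fold change -0.75, SE 0.087, adjusted p = 1.89e-05). Hook-associated flgL and motor-linked motD fell, with log2 fold changes of -1.22 (adjusted p = 9.63e-07) and -1.08 (adjusted p = 1.13e-06). The rod genes flgB and flgF rose, by 1.02 (adjusted p = 2.00e-06) and 0.93 (adjusted p = 2.12e-06). They are the first genes of clusters along which the fitted log2 fold change fell, by -1.51 from flgB to flgE and -2.26 from flgF to flgL, as it did from fliE to fliJ (-1.48) and from fliL to flhB (-0.62), clusters chosen after such slopes had been seen. Flagellar master regulator gene fleQ was at 386 ± 30.1 and 422 ± 12.5 RPKM (log2 fold change 0.13, SE 0.090, adjusted p = 0.228), and its sign turned to -0.10 with centring and -0.072 with quantile normalization. Chemotaxis genes fell in 17 of 33 cases and rose in 3, with a median of -0.31 (camera adjusted p = 0.00518; adjusted p = 0.766 with an estimated correlation), and 20 of them passed over all genes tested and 20 when adjusted over the list alone. The methylesterase gene cheB fell, with a log2 fold change of -1.36 (adjusted p = 2.78e-07), as did the receptor genes Pchl3084_2223 and Pchl3084_0418, with -1.47 (adjusted p = 8.40e-08) and -1.26 (adjusted p = 1.25e-06). Receptor gene Pchl3084_2399 rose (1.19 (adjusted p = 8.85e-07)). With voom on estimated reads the chemotaxis call ended, with 21 members and an adjusted p of 0.0787 (0.00331 to 0.0787 over all alternatives).

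Genes for cyclic di-GMP, the second messenger that sets motility against surface growth, changed both ways. In that list 22 of 53 genes fell and 8 rose, with a median log2 fold change of -0.17 (camera adjusted p = 0.0197; adjusted p = 0.766 with an estimated correlation), and 30 of them passed over all genes tested and 29 when adjusted over the list alone. With the replicate number as a block that call ended (adjusted p = 0.0730, over a range of 0.00457 to 0.0730 in all alternatives). A phosphodiesterase gene, Pchl3084_3056, fell from 139.7 ± 15.4 to 53.8 ± 0.0141 RPKM (log2 fold change -1.36, SE 0.101, adjusted p = 6.12e-07). The diguanylate cyclase gene Pchl3084_4715 rose (1.16 (adjusted p = 8.78e-07)), while the dual-domain gene Pchl3084_3655 (-0.96 (adjusted p = 2.28e-06)) and the PilZ gene Pchl3084_5134 (-1.34 (adjusted p = 3.78e-06)) fell. In the yfiBNR system, known to raise cyclic di-GMP in small-colony variants of related bacteria, yfiB rose from 169.7 ± 2.06 to 229.9 ± 3.10 RPKM (log2 fold change 0.44, SE 0.077, adjusted p = 4.86e-04). The repressor gene yfiR was at 360.5 ± 21.8 and 325 ± 4.12 RPKM (log2 fold change -0.15, SE 0.084, adjusted p = 0.150), and it passed as lower with centring (-0.38), quantile normalization (-0.34) and rescaling (-0.26). The cyclase gene yfiN, whose label here is dgcN, was at 127 ± 6.88 and 124 ± 4.04 RPKM (log2 fold change -0.034, SE 0.085, adjusted p = 0.749), and it passed as lower with centring (-0.27) and quantile normalization (-0.24) and was at 0.0067 with the replicate block or without wild type replicate 3.

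Surface structures had no common direction. Among 45 exopolysaccharide genes 22 rose and 12 fell, with a median log2 fold change of 0.26 (camera adjusted p = 0.692; adjusted p = 0.919 with an estimated correlation), whereas centring gave 15 higher and 20 lower and a median of 0.022, and 34 of them passed over all genes tested and 34 when adjusted over the list alone. The alginate regulator gene algQ rose (1.65 (adjusted p = 3.39e-08)), as did mucB (1.00 (adjusted p = 9.80e-07)), and algZ (-1.10 (adjusted p = 1.33e-06)) and an alginate lyase gene, Pchl3084_5509 (-1.43 (adjusted p = 2.69e-07)), fell. Alginate gene algD stayed near the filter, at 4.71 ± 0.676 and 5.51 ± 0.205 RPKM (log2 fold change 0.20, SE 0.212, adjusted p = 0.438), with -0.037 under centring and a call at 1.01 under quantile normalization. Of 81 genes for pili, fimbriae and large adhesins, 28 rose and 18 fell (camera adjusted p = 0.981; adjusted p = 0.989 with an estimated correlation), and 46 of them passed over all genes tested and 45 when adjusted over the list alone. That list differed in sign between measures: its mean was 0.26, its median 0.0020, camera pointed down and fry up, and the median was -0.23, -0.098 and -0.099 under centring, quantile normalization and rescaling. Higher and lower genes also changed balance there, with 21 and 37, 23 and 27, and 24 and 26 in the same order. The Flp pilus genes stood out, with cpaB rising from 21.2 ± 1.99 to 370.5 ± 32.5 RPKM (log2 fold change 4.06, SE 0.103, adjusted p = 1.47e-10), and the pilin gene Pchl3084_4531 (3.84 (adjusted p = 1.09e-09)) and the prepilin peptidase gene Pchl3084_4530 (3.45 (adjusted p = 1.34e-09)) rising too. A HecA-family adhesin gene, Pchl3084_2697, fell from 141 ± 4.62 to 16.4 ± 0.516 RPKM (log2 fold change -3.03, SE 0.086, adjusted p = 3.79e-10).

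Type VI secretion, a contact-dependent injection system, was lower in 21 and higher in 10 of 43 measured genes, with a median log2 fold change of -0.32 (camera adjusted p = 0.00744; adjusted p = 0.799 with an estimated correlation), and 31 of them passed over all genes tested and 32 when adjusted over the list alone. An Rhs gene (Pchl3084_0230, -1.61 (adjusted p = 3.84e-08)), a Vgr gene (Pchl3084_5819, -1.55 (adjusted p = 1.08e-07)) and the ATPase gene clpV2 (-1.39 (adjusted p = 8.43e-07)) fell. Runs in different clusters went in different directions. In 1 cluster tssK1 rose (1.21 (adjusted p = 5.00e-07)), and the run of 7 genes from tssB1 to tssF1 was higher by a median of 0.79. In the other the runs of 6 genes from fha2 to tssF2 and from Pchl3084_5833 to tssB2 were lower, with medians of -1.09 and -0.90. These 3 runs were chosen after their values were seen. A run is drawn by its direction, which fixes the sign of its median, and the clusters were not tested against each other. Type III secretion had 3 measured names, too few to test as a list. These were hrpB (-0.88 (adjusted p = 8.46e-05)), hrpA (-0.29 (adjusted p = 0.0206)) and pcrP (-0.40 (adjusted p = 0.0114)), all lower, of which hrpB and hrpA encode helicases with a shared symbol and pcrP a hypothetical protein. Without SCV replicate 2, pcrP ended at -0.34, and hrpA missed the threshold with the replicate block (-0.26) and without wild type replicate 3 (-0.26), SCV replicate 1 (-0.33) or SCV replicate 2 (-0.24).

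Respiration genes fell more often than they rose. Of 56 genes for respiration and ATP synthase 32 fell and 17 rose, with a median log2 fold change of -0.36 (camera adjusted p = 0.00244; adjusted p = 0.766 with an estimated correlation), and 49 of them passed over all genes tested and 50 when adjusted over the list alone. Cytochrome o oxidase genes cyoC, cyoD and cyoE fell, with log2 fold changes of -1.86 (adjusted p = 1.35e-08), -1.73 (adjusted p = 1.80e-08) and -1.58 (adjusted p = 3.74e-08). The complex I gene nuoI fell from 689 ± 43.7 to 184 ± 16.4 RPKM (log2 fold change -1.90, SE 0.092, adjusted p = 2.28e-08). Ribosomal protein and translation factor genes fell in 33 of 67 cases and rose in 21, with a median of -0.27 (camera adjusted p = 0.00674; adjusted p = 0.799 with an estimated correlation), and 54 of them passed over all genes tested and 54 when adjusted over the list alone. Quantile normalization ended that call (adjusted p = 0.164, over a range of 0.00194 to 0.164 in all alternatives). The strongest decreases were in rplV (-2.02 (adjusted p = 1.42e-08)), rpsS (-1.94 (adjusted p = 3.87e-08)), rpsC (-1.82 (adjusted p = 2.83e-08)) and rplP (-1.80 (adjusted p = 3.21e-08)), all of the S10 cluster. The change along gene clusters varied. Over 13 clusters of ribosomal protein or respiration genes, chosen after such slopes had been seen, the first gene lay between -1.45 (spc cluster) and 0.93 (rpsB to frr). The fitted change fell from start to end in 11 and rose in 2, the spc cluster (0.34) and rpsF to rplI (0.10). Among the first genes were cyoA at 0.37 (adjusted p = 0.00178), nuoA at -0.24 (adjusted p = 0.0173) and rpsJ at 0.13 (adjusted p = 0.230), and the fitted fall was -1.96, -0.46 and -1.73 along their clusters. The cyoA call ended with centring (0.14) and quantile normalization (0.12), the nuoA call without SCV replicate 1 (-0.24) or 2 (-0.25), and rpsJ turned to -0.10 with centring and passed at 0.24 with quantile normalization. Over 39 clusters in textbook order, listed after several such slopes had been seen, the fitted log2 fold change fell from the start to the end in 31 (exact sign test, 2-sided p = 0.000294; median -0.68). The 39 include clusters chosen for such slopes, so that p-value does not test whether clusters at large fall.

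**Figure D3:**
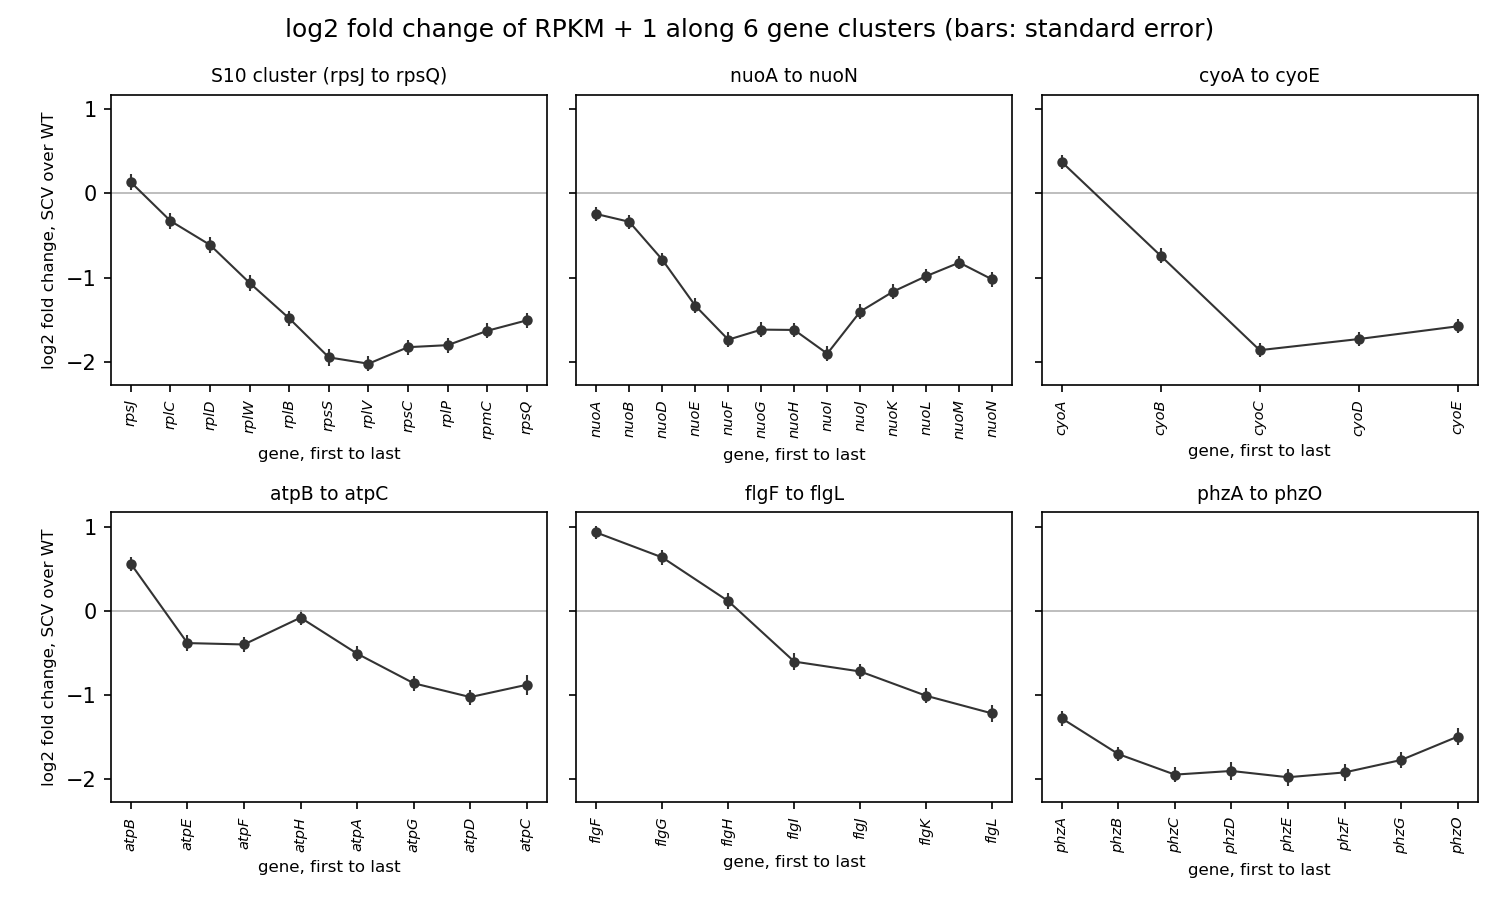
The log2 fold change of RPKM + 1 (SCV over wild type, bars are standard errors) for genes in order along 6 clusters, chosen after their values were seen. Fitted values fell along the S10, cyo, atp and flgF to flgL clusters, and values were low throughout the phenazine cluster. The lowest gene lay before the end in the S10 (rplV), cyo (cyoC), atp and nuo (nuoI) clusters.

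Transfer RNA genes were mostly higher. Of 85 genes for ribosomal and transfer RNA 58 rose and 8 fell, with a median log2 fold change of 1.01 (camera adjusted p = 5.35e-05; adjusted p = 0.766 with an estimated correlation), and 66 of them passed over all genes tested and 66 when adjusted over the list alone. By class, 57 of 72 transfer RNA genes rose and 8 fell, while 0 of 12 genes for 16S and 23S RNA passed (-0.28 to 0.19, median SE 0.911), and the list also took an enzyme gene by its name. The transfer RNA genes named by the rule were Pchl3084_1725 for glutamate (2.20 (adjusted p = 7.25e-09)), Pchl3084_1977 for alanine (1.86 (adjusted p = 1.48e-08)), Pchl3084_4281 for aspartate (1.59 (adjusted p = 6.82e-08)) and Pchl3084_2007 for valine (1.55 (adjusted p = 8.74e-08)). Copies of near-identical RNA genes may share reads, and the aligner is not given, so values of single copies are uncertain. Ribosomal RNA, depleted before sequencing, took 0.294%, 1.22% and 3.39% of reads in wild type and 0.516% and 2.35% in SCV, estimated from RPKM and gene length. The 6S RNA gene ssrS, chosen after its values were seen, rose from 15934 ± 3588 to 67559 ± 6626 RPKM (log2 fold change 2.10, SE 0.176, adjusted p = 1.51e-06). It ranked among the same 3 highest genes in every library, which sets its change to 0 under quantile normalization.

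Regulator, chaperone and other lists did not pass. Among 89 genes for global regulators and sigma factors 48 rose and 20 fell, with a median log2 fold change of 0.27 (camera adjusted p = 0.284; adjusted p = 0.890 with an estimated correlation), and 68 of them passed over all genes tested and 68 when adjusted over the list alone. Centring left 35 higher and 28 lower with a median of 0.038, and quantile normalization and rescaling 39 and 24 each, with medians of 0.13 and 0.16. FecI-family sigma factor gene Pchl3084_3048 rose (1.91 (adjusted p = 2.23e-07)), and relA, for the alarmone ppGpp, fell from 451 ± 3.02 to 206 ± 10.1 RPKM (log2 fold change -1.13, SE 0.079, adjusted p = 3.90e-07). Response regulator gene gacA rose (0.60 (adjusted p = 1.21e-04)), and its sensor gene gacS fell (-0.27 (adjusted p = 0.0188)), a call that ended without SCV replicate 1 (-0.29) or SCV replicate 2 (-0.25). Stationary-phase sigma factor gene rpoS did not pass (log2 fold change 0.12, SE 0.085, adjusted p = 0.230), with -0.11 under centring and a call at 0.22 under quantile normalization. For heat shock and protein folding 14 rose and 9 fell of 34 (camera adjusted p = 0.958; adjusted p = 0.989 with an estimated correlation), 23 of them passed over all genes tested and 23 when adjusted over the list alone, and the median of 0.085 became -0.15 with centring, 0.017 with quantile normalization and -0.016 with rescaling. Their counts of higher and lower genes were 9 and 13, 9 and 11, and 11 and 11. Without shared names 27 genes had a median of 0.21. An Hsp20 gene, Pchl3084_2153 (2.66 (adjusted p = 3.88e-08)), secB (1.69 (adjusted p = 4.16e-08)) and clpP (1.40 (adjusted p = 7.02e-08)) rose, and grpE fell (-1.06 (adjusted p = 5.66e-07)).

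Denitrification and arginine fermentation had 7 measured genes, 3 higher and 1 lower (camera adjusted p = 0.654; adjusted p = 0.890 with an estimated correlation), 4 of them passed over all genes tested and 4 when adjusted over the list alone, and the median of 0.14 became -0.090 with centring and 0.033 with rescaling. Without shared names 5 genes had a median of 0.46. Arginine deiminase gene arcA rose from 2838 ± 57.3 to 6183 ± 396 RPKM (log2 fold change 1.12, SE 0.094, adjusted p = 1.50e-06), arcC (0.46 (adjusted p = 6.12e-04)) and the nitrite reductase gene nirK (0.60 (adjusted p = 1.07e-04)) rose, and nosR, here a response regulator, fell (-1.35 (adjusted p = 3.05e-07)). Efflux pump genes were split, with 18 higher and 23 lower of 58 and a median of -0.21 (camera adjusted p = 0.113; adjusted p = 0.799 with an estimated correlation), and 41 of them passed over all genes tested and 41 when adjusted over the list alone. With centring they had 12 higher and 31 lower and a median of -0.45. The pump genes mdtC (-1.52 (adjusted p = 4.98e-07)) and Pchl3084_2725 (-1.38 (adjusted p = 6.08e-07)) fell, and corC (1.18 (adjusted p = 2.62e-07)) and Pchl3084_4142 (1.28 (adjusted p = 5.92e-07)) rose. In pump clusters chosen after such slopes had been seen, the first gene was higher and the last lower, at 0.89 and -1.52 in mdtABC, 1.23 and -0.83 in emhABC and 0.55 and -0.69 in mexEF-oprN. Sulfur starvation and sulfonate use had 13 higher and 9 lower of 42 (camera adjusted p = 0.536; adjusted p = 0.890 with an estimated correlation), with a median of -0.024, a mean of 0.026, camera pointing down and fry up, and 22 of them passed over all genes tested and 21 when adjusted over the list alone. The balance turned to 6 higher and 18 lower with centring, 8 and 11 with quantile normalization and 10 and 13 with rescaling (medians -0.26, -0.079 and -0.12). In it cysD (1.24 (adjusted p = 4.89e-07)), cysZ (0.93 (adjusted p = 1.26e-05)) and a sulfatase gene, Pchl3084_4221 (1.07 (adjusted p = 1.12e-06)), rose, and cysE fell (-0.81 (adjusted p = 2.32e-05)). Prophage, pyocin and bacteriocin genes had 27 higher and 9 lower of 57 (camera adjusted p = 0.504; adjusted p = 0.890 with an estimated correlation), with a median of 0.26, a mean of -0.00018, camera pointing up and fry down, and 36 of them passed over all genes tested and 36 when adjusted over the list alone. With centring 20 were higher and 12 lower and the median was 0.030. Without shared names 39 genes remained, 23 higher and 6 lower, with a median of 0.48. The R-pyocin holin gene hol rose (1.26 (adjusted p = 7.06e-07)), and the integrase genes Pchl3084_2951, Pchl3084_2946 and Pchl3084_2945 lay in the block near 0.

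A block of 39 neighbouring genes, from Pchl3084_2928 to Pchl3084_2966, was nearly silent in both SCV libraries. Wild-type means in it ran from 11.7 to 1080.0 RPKM, with a median of 88.2. In SCV, 20 of the 39 genes were listed at 0 in both libraries. The other genes reached at most 0.81 RPKM, except the first gene, Pchl3084_2928, at 3.92 and 4.20 RPKM. Reads estimated for the 32 block genes with a known length numbered 152282, 162074 and 116730 in the wild-type libraries, against 262 and 239 in the deeper SCV libraries. All 39 fell past the threshold, and no other gene of the genome had an SCV mean under 0.1 of its wild-type mean. The block held the toxin complex genes tcdA1 (265 ± 11.5 RPKM in wild type, 0.16 and 0.15 RPKM in the SCV libraries) and tcdC1 (209 ± 10.8 RPKM, against 0.080 and 0.040 RPKM). It also held 7 genes of transposase or integrase type and 22 hypothetical ones. The 12 genes with the lowest fold change by the rule all lay here. They were tcdA1, tcdC1, Pchl3084_2930, Pchl3084_2938, Pchl3084_2939, Pchl3084_2948, Pchl3084_2949, Pchl3084_2957, Pchl3084_2958, Pchl3084_2961, Pchl3084_2965 and Pchl3084_2966. The highest of them in wild type, Pchl3084_2948, was at 1045 to 1120.4 RPKM in its 3 libraries, against 0.81 and 0.51 RPKM in the SCV libraries. The gene before the block, Pchl3084_2927, rose from 21.3 ± 5.52 to 111 ± 14.7 RPKM (log2 fold change 2.36, SE 0.186, adjusted p = 9.49e-07), and the gene after it, Pchl3084_2967, fell from 269 ± 12.3 to 198 ± 5.23 RPKM (log2 fold change -0.44, SE 0.081, adjusted p = 6.17e-04). These neighbours were chosen after their values were seen.

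**Figure D4:**
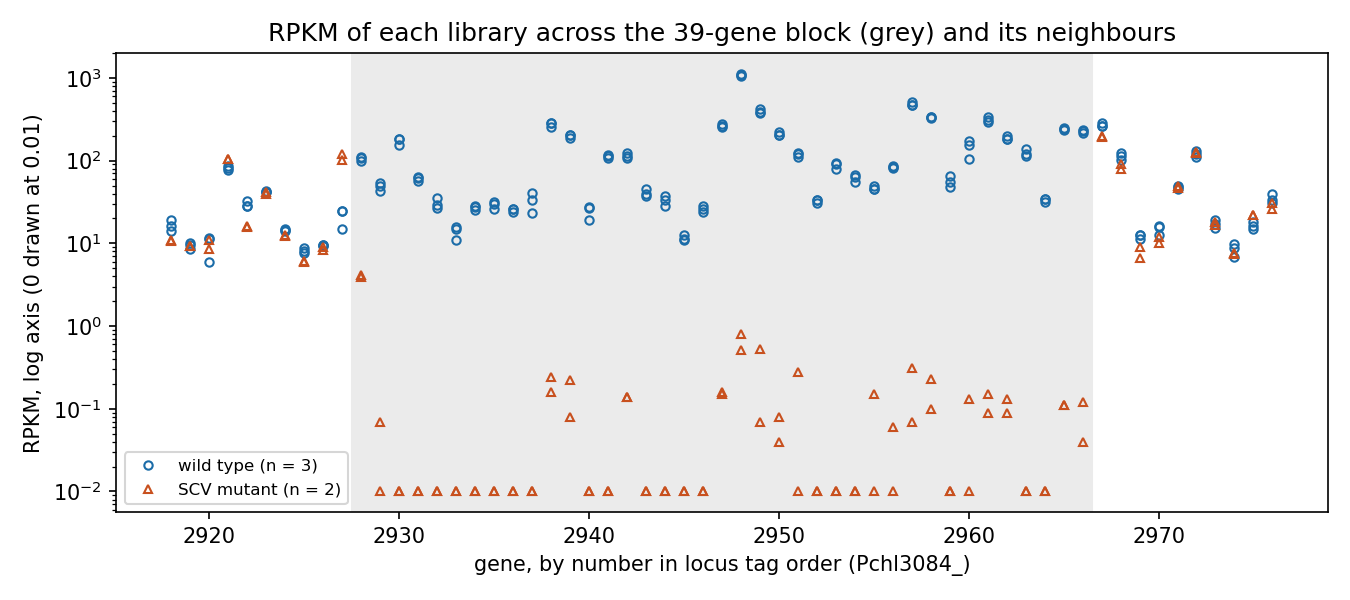
RPKM on a log axis for each wild-type library (circles, n = 3) and SCV library (triangles, n = 2), by gene number in locus tag order, with the 39-gene block in grey and values of 0 drawn at 0.01. Inside the block wild-type means lie between 11.7 and 1080.0 RPKM and every SCV value is at most 4.20 RPKM.

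Outside the block, among genes past the threshold with a mean of at least 20 RPKM and groups that do not overlap, the 12 lowest fold changes, chosen after the values were seen, took in Pchl3084_2697 and the ribosomal and phenazine genes rplV, rpsS, phzE and phzC. The gene yiiM fell from 3294 ± 271 to 674 ± 37.5 RPKM (log2 fold change -2.29, SE 0.097, adjusted p = 8.82e-09), and its product is annotated as a base analog detoxification protein. The aldehyde dehydrogenase gene ydcW (-2.20 (adjusted p = 8.27e-09)), the peptidoglycan-binding gene hxsA (-1.94 (adjusted p = 1.16e-08)) and the lipoprotein gene Pchl3084_2503 (-1.92 (adjusted p = 4.59e-08)) fell as well. A pentapeptide repeat gene (Pchl3084_5025, -2.29 (adjusted p = 3.52e-08)) and the hypothetical genes Pchl3084_4408 (-2.24 (adjusted p = 6.81e-07)) and Pchl3084_4314 (-2.04 (adjusted p = 8.97e-09)) completed these 12.

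Neighbouring genes changed together. There were 254 runs of at least 4 consecutive genes past the threshold in the same direction, 164 up and 90 down, holding 1576 genes. Shuffling the gene order 1000 times gave 90.9 runs on average and 116 at most (permutation p = 0.001, the smallest that 1000 shuffles can give). The longest, 46 genes from rsmZ (1.01 (adjusted p = 3.29e-04)) to recX (0.58 (adjusted p = 9.91e-04)), covered the tail genes of an R-type pyocin, a phage-tail-like weapon, and was higher by a median of 0.68. The block and its neighbours formed a lower run of 43 genes, from Pchl3084_2928 to Pchl3084_2970 (-0.41 (adjusted p = 0.0386)), whose last gene ended outside the threshold with the replicate block (-0.35) and when any library but wild type replicate 2 was left out (-0.52 to -0.30). Runs of 17 genes from Pchl3084_5808 (-0.38 (adjusted p = 0.00574)) to the type VI gene tssK2 (-0.72 (adjusted p = 3.36e-05)), and of 16 from Pchl3084_0460 (-0.50 (adjusted p = 5.84e-04)) to Pchl3084_0475 (-0.58 (adjusted p = 0.00105)), were lower, with medians of -0.72 and -0.89. The Pchl3084_5808 call ended without SCV replicate 2 (-0.34). Another 16 genes, from Pchl3084_4519 (0.25 (adjusted p = 0.0325)) to Pchl3084_4534 (0.62 (adjusted p = 0.00111)), held the Flp pilus genes and were higher by a median of 1.95, while the call of Pchl3084_4519 itself ended with centring (0.019), quantile normalization (0.042) and rescaling (0.14), without the trend in eBayes (0.25), and without any library but wild type replicate 1 (0.20 to 0.28). The ribosomal run of 14 genes from rpsN (-0.97 (adjusted p = 6.06e-05)) to rplC (-0.33 (adjusted p = 0.00886)) had a median of -1.49, and the complex I run of 13 from nuoA to nuoN (-1.02 (adjusted p = 2.69e-06)) one of -1.16. The rplC call ended without SCV replicate 2 (-0.27). A run of 13 from moaC (0.28 (adjusted p = 0.0185)) to the amino acid transporter gene aapP (1.51 (adjusted p = 1.49e-07)) was higher, with a median of 1.10, and the moaC call ended with centring (0.048), quantile normalization (0.069) and rescaling (0.17), and without wild type replicate 2 (0.26) or SCV replicate 1 (0.22).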

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

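The counts of genes kept their size under all alternatives run. From 3651 genes past the threshold the range was 2943 to 3903, and from 1028 with at least 2-fold change it was 768 (pseudocount of 10 RPKM) to 1063. The 254 runs ranged from 191 to 281. Leaving out each library in turn gave 2943 to 3681 genes, 1024 to 1045 with at least 2-fold change, 11 lists and 191 to 261 runs. Where an SCV library is left out, the lone SCV sample is assumed to vary like the wild type. No alternative called a gene in the opposite direction to the call as deposited. The list count of 11 became 0 when camera used an estimated correlation. That form raises the variance of most lists' statistics and also takes its p-values on the 3 residual degrees of freedom. The oxidative stress list, which passed in neither form, had the lowest estimated correlation, 0.012 against the preset 0.01. Its camera p went from 0.223 to 0.321. Among the 11 lists that passed, the estimates ran from 0.019 to 0.40. The camera p went from 0.0027 to 0.512 for ribosomal proteins (0.40) and from 0.0033 to 0.456 for type VI secretion (0.38). For cyclic di-GMP (0.019) it went from 0.0099 to 0.108. The higher correlations and the few degrees of freedom both raise p, and their shares were not separated. The 0 therefore does not decide for or against the 11, whose calls hold only where members are taken as nearly independent. The list count was 10 with quantile normalization, with voom and without RNA genes that code for no protein (which removes the list of ribosomal and transfer RNA). Alternatives chosen only after the data were seen were voom, leaving out RNA genes that code for no protein, the estimated correlation, lists without shared names, and leaving out the silent block, which gave 3602 genes and 989 with at least 2-fold change. The edgeR fit, planned in case the table held raw counts, was not run.

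The replicate number used as a block (replicate block) gave 3600 genes (2267 higher, 1333 lower), 1030 with at least 2-fold change, 11 lists and 249 runs. Wild type replicate 3 has no SCV library of its number, so the fold changes equal those without it, and 1 residual degree of freedom was left. Under the replicate block the cyclic di-GMP list moved to an adjusted p of 0.0730 (0.00457 to 0.0730 over all alternatives) and the oxidative stress list to 0.0291 (0.0291 to 0.453). The labels do not pair the cultures, and with 2 shared numbers the deviations correlated at 0.26 for number 1 and 0.12 for number 2, while wild type replicate 3 and SCV replicate 2 gave 0.19. The SCV deviations mirror each other by construction.

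Of 148 named genes, 138 passed, and in 2771 comparisons with alternatives 2711 kept direction and side of the threshold, 32 lost the call, 12 gained it and 16 turned sign. All that turned sign were not past the threshold as deposited. Centring turned fleQ to -0.10, phzI to -0.21, rpoS to -0.11, algD to -0.037, rnpB (0.0092 as deposited) to -0.23 and rpsJ to -0.10. Quantile normalization turned fleQ to -0.072 and phzI to -0.17, and rescaling turned phzI to -0.085. The replicate block turned dgcN to 0.0067 and rnpB to -0.044, and array weights turned rnpB to -0.012. Leaving out each library in turn gave -0.070 to 0.0067 for dgcN, above 0 without wild type replicate 3, and -0.060 to 0.093 for rnpB, below 0 without wild type replicate 1 or 3 or SCV replicate 2. The cause was not tested, except that centring subtracts 0.23 from each value. Depth limits the lowest values, where 1 read on a 1-kb gene is worth up to 0.0923 RPKM, and 230 genes under the filter were not tested.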

Other observations

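Some clusters of breakdown and division genes, chosen here after their values were seen and not tested as lists of their own, moved in both directions. The cluster hmgA-fahA-maiA for tyrosine breakdown had a median log2 fold change of 3.66, prpB-prpC-acnD for propionate breakdown 2.44, and bkdA1 to bkdC for branched-chain keto acids 1.96. The run of 12 genes from Pchl3084_0400 to pip, which holds the histidine utilization genes, was higher by a median of 1.36. The run of 5 from catI to pcaG, for aromatic breakdown, was lower by a median of -1.50. The run of 12 genes from ftsZ to ftsI, which holds division genes, fell with a median of -0.95. A run is drawn by its direction, and the neighbouring division gene ftsL, outside it, was at -0.19. In the run ftsZ, for the protein of the division ring, went from 2163 ± 37.3 to 1413 ± 126 RPKM (SD, n = 3 and n = 2; limma adjusted p = 1.22e-04), and ftsA and ftsI had log2 fold changes of -0.93 (adjusted p = 4.12e-06) and -0.60 (adjusted p = 6.46e-05). The division genes minCDE, which place the division site, were higher instead, with a median of 1.40.

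The small RNAs of the Gac-Rsm pathway, which bind the translational repressors of secondary metabolism, were higher in SCV. By limma, rsmX rose by a log2 fold change of 1.09 (adjusted p = 2.75e-04), rsmY by 1.02 (adjusted p = 8.19e-05) and rsmZ by 1.01 (adjusted p = 3.29e-04), in 2 of 2 SCV libraries each. Other short RNAs rose with them: the median over 72 transfer RNA genes was 1.43, and 6S RNA ssrS had a log2 fold change of 2.10 (adjusted p = 1.51e-06). Recovery of short RNAs was not tested for the rsm genes and stays open. Of the abundant small RNAs, 2 had no call: transfer-messenger RNA ssrA was at 426700.0 ± 34978 RPKM in wild type and 386742 ± 22528 in SCV (log2 fold change -0.14, adjusted p = 0.583), and RNase P RNA rnpB at 178370.0 ± 18699 and 179086 ± 12215 (0.0092, adjusted p = 0.972).

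In the patterns that follow, all tests of the silent block and the test of short-RNA recovery were chosen after the result was seen, and the tests on gene length, on variation between libraries and on a few abundant genes were written before their values were seen.

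The 39 silent genes from Pchl3084_2928 to Pchl3084_2966 did not come from shallow SCV libraries, since the shallower SCV library was 1.36 times as deep as the deepest wild-type one. Reads that cannot be placed in repeated elements do not account for them either, because 100% of the 39 genes had a wild-type mean of at least 5 RPKM. A candidate explanation is loss of the block from the SCV genome, but a silenced block would give the same values. Neither can be told from the other by the 0 genes outside that lay under 5% of their wild-type mean (the lowest was at 11.6%, and the highest inside at 3.82%), since the block was drawn by the same ratio. DNA was not analysed here, so both stay open, as does a trace of wild-type reads as the source of the 262 and 239 SCV reads.

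The log2 fold change fell along 31 of 39 gene clusters, which were listed after several such slopes had been seen. With the trend on coding length taken out it still fell along 30 (median -0.78; exact sign test, 2-sided p = 0.00107). For these clusters, that argues against length bias as the whole cause. Since some clusters were chosen for the slope, the p-value does not measure how common the slope is. RNA quality that varies from library to library is argued against as well: the largest median change in a wild-type library against the other 2 was 0.0583, against -0.68 in SCV. The same 31 count was found with each SCV library alone. A difference in RNA decay, in transcript completion or in library making shared by all libraries of a group was not tested and may account for the slope. Lower values at the ends of clusters therefore bear on the values for respiration, ribosomal proteins, flagella and efflux pumps.

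Of 72 transfer RNA genes 57 were higher in SCV and 8 lower, with a median log2 fold change of 1.43. If recovery of short RNAs depended on length alone, genes of 1 length would move alike. Over 28 genes of 76 bases the SD was 6.09 times the median standard error, so these did not. That spread does not bear on the rise they share, so recovery stays open as its cause. The labels give a size selection of 200 to 300 bp, and its effect on RNAs this short was not tested. After genes above 5000 RPKM were left out and the libraries rescaled, the median was still 1.32, which argues against a few genes taking most of the reads. For lysine, 5 of 7 copies were lower, between -0.98 and -0.74. Recovery of short RNAs, reads shared between near-identical copies and a biological difference between the strains stay open.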
